A study of Mus musculus with 15 samples.

How the data were processed

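RNA sequencing had been performed on 15 mouse libraries of sorted cells, in 5 groups of 3. The first 9 libraries came from C57BL/6 mice in the steady state. They held 2 sorted macrophage subsets of visceral fat, CX3CR1-high CCR2-high (CCR2-high here) and CX3CR1-low CCR2-low (CCR2-low here), and cells labelled blood monocytes. The other 6 libraries were CCR2-low macrophages of the same tissue, 3 from mice with myocardial infarction (MI) and 3 from sham-operated mice. RNA of the sorted cells was extracted with a PicoPure kit, per the submitters' protocol. Cell numbers, ages, the time after MI and the gates themselves are not given in the sources used here.

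For the steady-state libraries the authors deposited a table of TPM (transcripts per 1e6 transcripts) per library, on the linear scale, per the file headers. In each of the 9 columns the values summed to 1000000 over 28347 genes. The same table carries, per the file headers, the authors' log2 fold changes and adjusted p-values for the 3 comparisons, and 3 further deposited lists hold the genes under the authors' limit of 1e-04. Their test is not given in the sources used here. For the MI and sham libraries the deposited table gives RPKM (reads per kilobase of gene and 1e6 reads), per the file headers, with column names that record paired and trimmed reads. Its columns summed to 382465 to 423718 over 48709 genes, of which 21809 were above 0 in at least 1 library. The build was mm10, per the submitters' processing notes, and the aligner and annotation release are not given in the sources used here.

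Gene IDs were matched to GENCODE M21, which is on the same build, for 27754 genes of the steady-state table and 48349 of the MI table, and this annotation supplied chromosome, start and end. For the steady state, 26 symbols had been turned into calendar dates, and these genes were named by their IDs.

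Depth was not stated. Because low TPM and RPKM values were whole multiples of 1 read over the gene length, read numbers were worked back for genes whose values were whole (within 0.05 of a whole number) in the libraries. This gave 16.33 to 22.04 M reads (M, 1e6) per steady-state library over 17572 genes and 32.68 to 43.63 M per MI or sham library over 16069 genes. Of the low values, 75.4 to 77.5% and 81.6 to 82.6% were whole within that tolerance. These totals leave out the other genes, so they are lower bounds on depth. For the MI and sham libraries, the read totals in the RPKM denominator, worked back from the same values, were 57.6 to 75.6 M.

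Each comparison used limma (version 3.58.1 in R 4.3.3) on log2(value + 1), with eBayes and an intensity trend, over genes at 1 or more in at least 3 libraries of the fit: 15467 genes in the 9 steady-state libraries, which shared 1 estimate of the spread, and 9607 genes in the 6 MI and sham libraries. Genes were called at a two-sided Benjamini-Hochberg adjusted p below 0.05. The tables were never tested against each other, since their units and processing differ. Before the data were examined, 51 gene lists were fixed, covering macrophage functions, other cell types that the tissue or gates could hold, and signs of RNA quality. They were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated per list, with adjustment over the lists of 1 comparison. Lists with fewer than 5 measured members were not tested, which left 50 lists in the steady-state comparisons and 46 in the MI comparison. For each list the number of called members is also given with adjustment over the list alone.

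Named genes followed a rule also fixed before the data were examined. It took the transcripts of the 2 sort markers. It took the 6 called genes with the largest log2 fold change in each direction. These needed a mean of at least 10 in the higher group, no overlap between libraries and values above 0 in both groups, and unnamed gene models and receptor segments were left out. It also took, of each list described, up to 4 measured members with the smallest p. Where no gene passed, the 4 with the smallest p in each direction were taken. Some genes that meet this rule are not reported here. The position of CCR2-high libraries between the other steady-state groups was the median, over 11892 genes called between CCR2-low and labelled monocyte libraries in a fit without the CCR2-high libraries, of the fraction of the log2 difference covered. For reference, each CCR2-low library in turn was placed on an axis drawn without it, a step added after the position was seen.

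The fits were tested on simulated data with 200 changed genes. At a simulated log2 change of 1, 83, 86.5, 84.5 and 72% of those genes were recovered in the CCR2-high against CCR2-low, CCR2-high against monocyte, CCR2-low against monocyte and MI against sham designs. At a log2 change of 0.5 the shares were 0, 4.5, 0 and 0%, and at 2 they were 98, 98, 98 and 92.5%. Up to 10% of the calls were false. Noise was drawn independently for each gene and library, and changes were placed only in more abundant genes. Recovery in the real libraries may therefore be lower. In the steady-state fits far more than 200 genes were called, which eases the adjusted threshold, so recovery there may also be higher. Ccr2 was called at a log2 fold change of 0.36 between CCR2-low and labelled monocyte libraries.

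The settings varied were a pseudocount of 0.1 or 5, no filter, a mean of at least 5, quantile normalization, scaling by trimmed mean of M values (TMM), robust eBayes, a replicate block, a fit of only the 6 libraries compared, a limit on fold change, and leaving out each library in turn. Added after the data were seen were limma's voom on the reads worked back, a score for CCR2-high genes as a covariate in the MI comparison, and camera under settings planned for genes only. Libraries of 1 replicate number did not deviate together from their group means, as correlations of these deviations showed. With 3 libraries per group this cannot exclude that they share mice or a sort. No block was used in the reported fits. For MI and sham libraries the number in the title differs from the number in the description for several libraries, and the title's number is used. The columns of sham replicates 1 and 2 carry the same S2 in their names, where the other columns carry S1, S4, S5 and S6, so either may have been relabelled or sequenced again. They correlated at 0.991 with each other and at 0.994 and 0.992 with sham replicate 3, so their values are not copies, and both were kept; a difference between runs was not tested. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6 for reading the files.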

Results

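The data are RNA-seq expression values for 15 libraries of sorted mouse cells, 3 per group. Steady-state groups were CCR2-high and CCR2-low macrophages of visceral adipose tissue and libraries labelled blood monocytes, in TPM. The surgery groups were CCR2-low macrophages after MI and after sham, in RPKM. Reads worked back ranged from 16.33 to 22.04 M (M, 1e6) in the steady-state libraries and from 32.68 to 43.63 M in the MI and sham libraries. Values are given as mean ± SD over the 3 libraries of a group, and every adjusted p of a gene is from limma.

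The transcripts of the sort markers were read first, because the gates were set on their proteins and they check the labels. Ccr2 (ENSMUSG00000049103, mm10 chromosome 9, 124101950 to 124113557) averaged 451 ± 18.2 against 76.1 ± 8.79 TPM in CCR2-high against CCR2-low libraries, and 58.9 ± 6.01 TPM in the libraries labelled blood monocytes. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) averaged 67 ± 13 against 2.02 ± 0.485 TPM in the same comparison and 15.3 ± 4.63 TPM in the labelled monocytes. Both were higher in CCR2-high than in CCR2-low libraries, with log2 fold changes of 2.56 (SE 0.11, adjusted p = 1.27e-06) and 4.48 (SE 0.21, adjusted p = 2.25e-06). After surgery, Ccr2 was 20.8 ± 11 against 36.6 ± 4.93 RPKM, adjusted p = 0.668, and Cx3cr1 was 14.2 ± 7.87 against 20.8 ± 4.18 RPKM, adjusted p = 0.781, in MI against sham libraries. MI replicate 1 had the lowest values, at 8.09 RPKM for Ccr2 and 5.11 RPKM for Cx3cr1. With RPKM brought to the total of TPM, a step added after the values were seen, Ccr2 was at 76.2 to 97.6 in sham and 21.2 to 68.4 in MI libraries, against 66.3 to 83.2 in steady-state CCR2-low and 436 to 471 in CCR2-high libraries. Cx3cr1 was at 44.3 to 61.9 in sham and 13.4 to 46.5 in MI libraries, nearer to steady-state CCR2-high (52.6 to 78.1) than to CCR2-low libraries (1.59 to 2.55) in sham. A score of 227 CCR2-high minus 283 CCR2-low genes was 0.87 to 1.21 in sham and -0.88, 0.25 and 0.81 in MI libraries, against -1.82 to -1.42 in steady-state CCR2-low and 1.24 to 1.71 in CCR2-high libraries. The score genes were chosen from the steady-state contrast, which places steady-state CCR2-low libraries at an extreme. Labelled monocytes scored 2.11 to 2.25, above CCR2-high macrophages, so a high score is not particular to CCR2-high cells. The score took RPKM and TPM as they were, so the surgery and steady-state scores are only roughly comparable. The mice differed as well: Xist was at 3.17 to 8.02 RPKM and Ddx3y was listed at 0 in the surgery libraries, while steady-state macrophages had Xist listed at 0 and Ddx3y at 43.59 to 61.07 TPM. The surgery libraries are therefore called CCR2-low after their labels only.

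**Figure D1:**
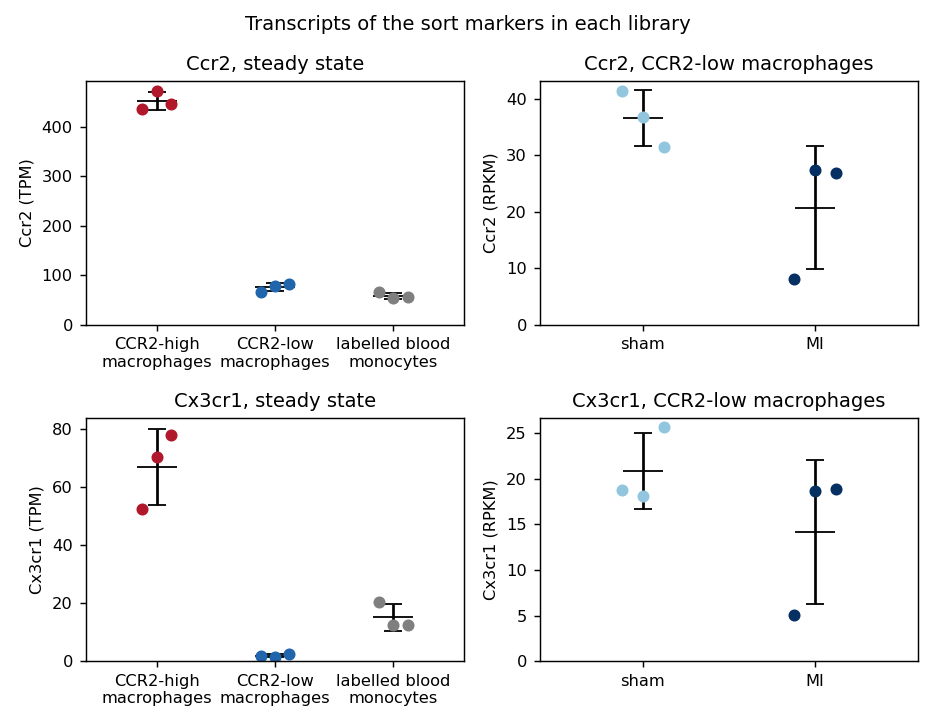
Ccr2 and Cx3cr1 in each library, in TPM for the steady state (left) and RPKM for CCR2-low macrophages after sham or MI (right); points are libraries, and bars give the mean and SD of 3. Ccr2 averaged 451 TPM in CCR2-high and 76.1 TPM in CCR2-low macrophages, and MI replicate 1 is the lowest point of both right panels.

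CCR2-high and CCR2-low macrophages were compared to ask how the 2 subsets of the tissue differ. CCR2-high macrophages held more transcript of cell-cycle genes, of MHC class II antigen presentation, and of cytokine genes such as Il1b and Tnf. CCR2-low libraries held more transcript of resident-macrophage genes such as Timd4, of genes typical of large peritoneal macrophages, and of complement genes such as C4b. They also held more of fibroblast, endothelial and mesothelial markers, and which cells these transcripts came from was not tested. Of 15467 genes tested, 2733 were called, 1381 higher and 1352 lower in CCR2-high, and 845 of them had an absolute log2 fold change of at least 1 (337 higher, 508 lower). Of the 50 lists tested, 25 passed the camera test at the preset correlation, 14 higher and 11 lower, and 0 with an estimated correlation.

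The called genes with the largest increase in CCR2-high included Cx3cr1. Spp1, which encodes osteopontin, averaged 105 ± 112 against 3.35 ± 3.39 TPM (log2 fold change 4.34, adjusted p = 0.00145). The signal-regulatory gene Sirpb1a averaged 82.8 ± 29.1 against 3.42 ± 1.83 TPM (log2 fold change 4.26, adjusted p = 4.53e-05), and Sirpb1c and Sirpb1b had log2 fold changes of 4.13 and 4.02. Chil3, a chitinase-like secreted protein, averaged 49.6 ± 12.4 against 4.12 ± 6.54 TPM (log2 fold change 4.12, adjusted p = 0.00276). Among the largest decreases, Saa3, an acute-phase protein, averaged 163 ± 124 against 2967 ± 3825 TPM (log2 fold change -3.60, adjusted p = 0.0119). The aminopeptidase gene Enpep averaged 4.19 ± 3.17 against 56.7 ± 23.7 TPM (log2 fold change -3.56, adjusted p = 0.000465). Cd209b, a C-type lectin gene, averaged 38 ± 27 against 322 ± 99.8 TPM (log2 fold change -3.22, adjusted p = 0.00048). Ltbp1 averaged 1.39 ± 0.35 against 23.3 ± 14.1 TPM (log2 fold change -3.21, adjusted p = 0.0002). Prg4 averaged 37.9 ± 14.4 against 376 ± 208 TPM (log2 fold change -3.19, adjusted p = 0.000286). Selp, which encodes P-selectin, averaged 4.28 ± 2.08 against 45 ± 22.7 TPM (log2 fold change -3.08, adjusted p = 0.000253). Over all genes tested, 37.7% showed no overlap between libraries of the 2 groups, where chance gives 10%. The SD of Spp1 and of Saa3 exceeded the mean of their higher group, and the Saa3 call was lost without a filter (adjusted p = 0.0566) and with robust eBayes (adjusted p = 0.0551). The 3 Sirpb1 genes are near-identical in sequence, so reads may not be assigned to them separately.

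Resident-type macrophage genes were lower in CCR2-high macrophages. In the resident macrophage list 21 of 26 measured members were lower in CCR2-high and 0 higher (23 lower when adjusted over the list alone), with a median log2 fold change of -1.40 (adjusted p = 1.23e-19, and adjusted p = 0.307 with an estimated correlation). Timd4, a receptor for apoptotic cells, averaged 33.2 ± 2.03 against 208 ± 20.2 TPM, log2 fold change -2.61, SE 0.11, adjusted p = 1.27e-06. Ninj1 (357 ± 31.5 against 899 ± 107 TPM, log2 fold change -1.33), Ltc4s, leukotriene C4 synthase (82.7 ± 0.924 against 233 ± 32.7 TPM, log2 fold change -1.47), and Fcna, a ficolin (258 ± 44.4 against 1525 ± 321 TPM, log2 fold change -2.55), were lower as well. Of the large peritoneal macrophage list, which shares 3 genes with the resident list, 17 of 18 were lower and 0 higher, as many as when adjusted over the list alone. Its median was -2.58 (adjusted p = 1.06e-17, and adjusted p = 0.307 with an estimated correlation), with Fcna, Ltbp1, Selp and Timd4 as its smallest p values. Complement components were lower in 6 of 17 members and higher in 0 (7 lower adjusted over the list alone; adjusted p = 2.53e-05, and adjusted p = 0.307 with an estimated correlation). These included C4b (log2 fold change -2.68, adjusted p = 3.94e-06) and the alternative-pathway regulator Cfp, properdin (978 ± 22.3 against 1506 ± 199 TPM, log2 fold change -0.61). C4b and its paralog are close in sequence.

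Monocyte genes went mainly the other way. Of the classical monocyte list, 8 of 19 members were higher and 2 lower (9 and 3 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.0108, and adjusted p = 0.331 with an estimated correlation). Ccr2 itself is a member, as are Ms4a4c (39 ± 2.65 against 4.99 ± 1.2 TPM, log2 fold change 2.76, adjusted p = 6.15e-06), Gpr141 (3.00) and Plac8 (12.4 ± 1.52 against 2.84 ± 1.05 TPM, log2 fold change 1.84). Of the non-classical monocyte list, 8 of 17 were higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.000185, and adjusted p = 0.331 with an estimated correlation). Its members Cx3cr1, Treml4 (8.1 ± 4.09 against 0.261 ± 0.171 TPM, log2 fold change 2.77, adjusted p = 0.000191) and Spn, which encodes CD43 (3.37 ± 0.405 against 1 ± 0.208 TPM, log2 fold change 1.13), were among the higher ones. Both lists hold a gene of a sort marker. In the lipid-associated macrophage list 8 of 20 were higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 0.00129, and adjusted p = 0.471 with an estimated correlation). Acp5 averaged 42.3 ± 11.8 against 12.1 ± 2.37 TPM, log2 fold change 1.71. Lgals3, galectin-3, averaged 778 ± 272 against 284 ± 25.6 TPM, log2 fold change 1.40, and the lipid receptor gene Trem2 44 ± 14.5 against 21.1 ± 1.87 TPM, log2 fold change 0.98.

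Antigen presentation and inflammatory genes were higher in CCR2-high macrophages. Of the MHC class II presentation list, 11 of 15 members were higher and 0 lower, as when adjusted over the list alone, with a median of 0.93 (adjusted p = 5.54e-07, and adjusted p = 0.32 with an estimated correlation). H2-Ab1 averaged 11290 ± 2428 against 5139 ± 261 TPM, log2 fold change 1.11, and H2-DMb1, part of the peptide-loading chaperone, 1031 ± 171 against 441 ± 22.1 TPM, log2 fold change 1.21, adjusted p = 0.000255. Inflammatory cytokine genes were higher in 8 of 18 and lower in 1 (11 and 1 adjusted over the list alone; adjusted p = 8.94e-05, and adjusted p = 0.346 with an estimated correlation). Il1b averaged 1012 ± 258 against 198 ± 89.3 TPM, log2 fold change 2.41, adjusted p = 0.000427. Tnf averaged 719 ± 83 against 249 ± 31.4 TPM, log2 fold change 1.52. Nlrp3, the inflammasome sensor, averaged 83.5 ± 2.62 against 35.3 ± 7.89 TPM, log2 fold change 1.24. Among NF-kB targets 10 of 21 were higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 1.7e-07, and adjusted p = 0.346 with an estimated correlation). Traf1 (19.6 ± 2.36 against 6.54 ± 1.53 TPM, log2 fold change 1.47) and the survival gene Bcl2a1d (942 ± 193 against 301 ± 96.5 TPM, log2 fold change 1.67) were among them. Chemokine genes split, with 10 of 25 higher and 5 lower (11 and 6 adjusted over the list alone; adjusted p = 0.0402, and adjusted p = 0.39 with an estimated correlation). Ccl4 (log2 fold change 2.50, adjusted p = 6.59e-05), Ccl3 (1.83) and Cxcl16 (1.22) were higher. Ccl24, an eosinophil attractant, was lower, at 225 ± 54.5 against 733 ± 52.7 TPM, log2 fold change -1.73, adjusted p = 0.000204. The chemokine list no longer passed under 4 of 15 alternatives, the highest adjusted p being 0.24 without CCR2-high replicate 3.

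Cell cycle, cholesterol biosynthesis and catecholamine handling lists also differed. Of the cell cycle list, 32 of 40 members were higher in CCR2-high and 0 lower (37 and 0 adjusted over the list alone), with a median of 0.96 (adjusted p = 1.42e-19, and adjusted p = 0.33 with an estimated correlation). The replication licensing genes Mcm2 (log2 fold change 1.30, adjusted p = 0.000307) and Mcm5 (log2 fold change 1.29, adjusted p = 0.000655) were examples. Stmn1 (83.9 ± 19.1 against 34.9 ± 4.84 TPM, log2 fold change 1.23) and the mitotic gene Ube2c (8.67 ± 2.35 against 2.64 ± 0.457 TPM, log2 fold change 1.39) were others. Cholesterol biosynthesis genes were higher in 10 of 22 and lower in 0 (11 and 0 adjusted over the list alone; adjusted p = 1.44e-06, and adjusted p = 0.331 with an estimated correlation). Fdps (48.6 ± 7.07 against 27.1 ± 3.02 TPM, log2 fold change 0.81) and Cyp51 (27.3 ± 4.14 against 12.9 ± 1.81 TPM, log2 fold change 1.02) were examples. Of 6 measured genes of catecholamine handling and adrenergic receptors, 3 were lower and 0 higher, as when adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.331 with an estimated correlation). Maoa, which breaks down noradrenaline, averaged 14.4 ± 5.07 against 36.5 ± 9.39 TPM (log2 fold change -1.30, adjusted p = 0.00529). Adrb1 was not called, at 1.84 ± 0.489 against 2.76 ± 1.17 TPM, adjusted p = 0.33. The list missed its threshold without a filter (adjusted p = 0.0679).

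Markers of other cell types differed between the subsets. CCR2-high libraries were lower in 14 and higher in 1 of 18 fibroblast and preadipocyte markers (14 and 1 adjusted over the list alone; adjusted p = 3.62e-08, and adjusted p = 0.33 with an estimated correlation). The matrix genes Dcn (7.96 ± 5.24 against 61.5 ± 16.7 TPM, log2 fold change -2.92, adjusted p = 0.0004) and Sparc (17.9 ± 6.55 against 55.1 ± 9.69 TPM, log2 fold change -1.61) were examples. Endothelial and mural markers were lower in 20 of 24 and higher in 0 (22 lower adjusted over the list alone; adjusted p = 3.8e-14, and adjusted p = 0.327 with an estimated correlation). Cav1 (16.2 ± 3.66 against 46.7 ± 4.18 TPM, log2 fold change -1.49) and Gpihbp1 (14.8 ± 3.34 against 50.5 ± 14.3 TPM, log2 fold change -1.69) were examples. Mesothelial markers were lower in 8 of 14 and higher in 0 (9 lower adjusted over the list alone; adjusted p = 1.44e-06, and adjusted p = 0.331 with an estimated correlation). Msln, mesothelin (0.151 ± 0.263 against 1.8 ± 0.409 TPM, log2 fold change -1.29), and Slpi (119.5 ± 67.6 against 791 ± 436 TPM, log2 fold change -2.73) were examples. Of the adipocyte list, 8 of 14 were lower and 2 higher (9 and 2 adjusted over the list alone; adjusted p = 0.00558, and adjusted p = 0.307 with an estimated correlation). Aqp7 was lower (3.94 ± 1.04 against 10.9 ± 1.87 TPM, log2 fold change -1.28), and Pparg, also active in macrophages, was higher (45.4 ± 16.7 against 13.4 ± 2.85 TPM, log2 fold change 1.65). That list missed the threshold with a mean of at least 5 (adjusted p = 0.107). As to RNA composition, ribosomal protein genes were higher in 42 of 78 and lower in 0 (58 higher adjusted over the list alone; median 0.38, adjusted p = 8.68e-18, and adjusted p = 0.428 with an estimated correlation). Rps26 (367 ± 27.1 against 238 ± 18.2 TPM, log2 fold change 0.62) was an example. Mitochondrially encoded genes were lower in 13 of 15 and higher in 0 (15 lower adjusted over the list alone; median -0.53, adjusted p = 7.88e-09, and adjusted p = 0.331 with an estimated correlation), such as mt-Nd2 (1028 ± 57.8 against 1759 ± 149 TPM, log2 fold change -0.77).

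No list of this comparison passed with an estimated correlation, where the lowest adjusted p was 0.307. The count of 2733 genes fell to 1481 without CCR2-high replicate 1, 1800 without CCR2-high replicate 3, 1580 without CCR2-low replicate 1 and 1612 without CCR2-low replicate 3. In the authors' own values, 193 genes lay under their limit of 1e-04 (105 higher, 88 lower in CCR2-high). Of the 182 tested here, 181 were called in the same direction and 0 in the opposite one. That limit is far stricter than the 0.05 used here, so a large overlap was likely. At an adjusted p below 0.05 the authors' values gave 609 genes, against 2733 called here.

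**Figure D2:**
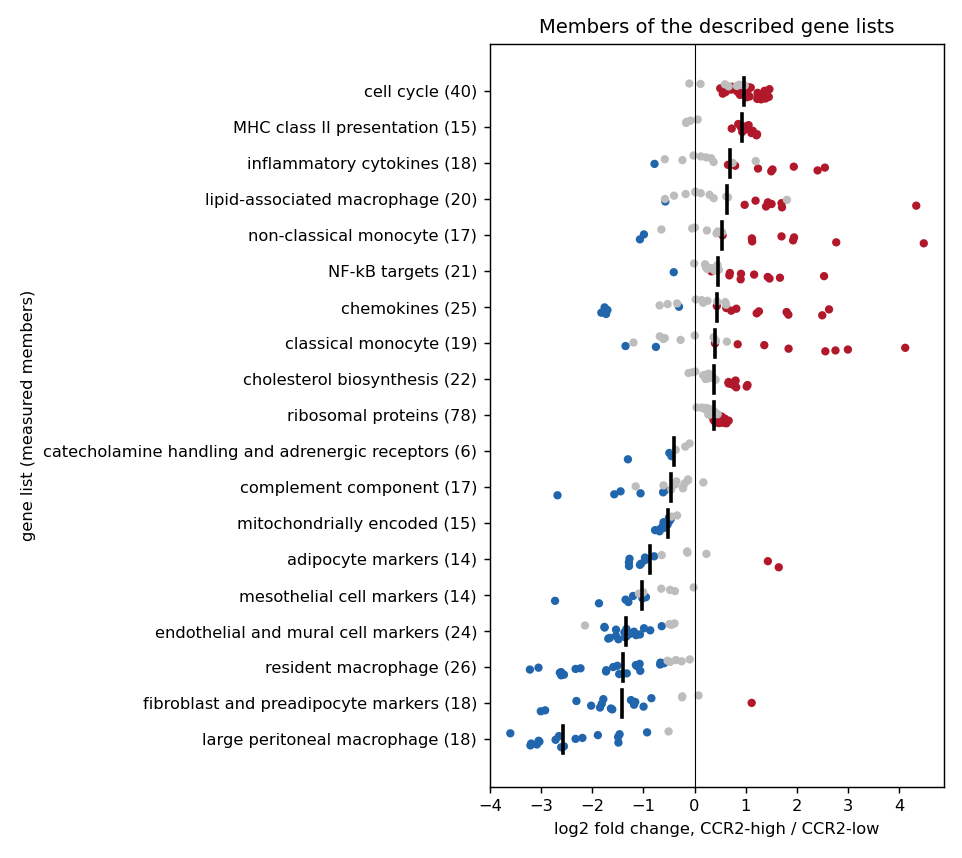
Log2 fold change of each measured member of the 19 described gene lists, CCR2-high against CCR2-low macrophages; red points were called higher, blue called lower, gray not called, and black bars are list medians. The medians run from -2.58 for large peritoneal macrophage genes to 0.96 for cell cycle genes.

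The macrophage subsets were next compared with the libraries labelled blood monocytes, to ask how far each lies from a circulating cell. In these libraries the most abundant transcripts included genes of primary granules, which neutrophil and monocyte precursors express. Mpo, myeloperoxidase (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), averaged 11290 ± 1559 TPM and ranked 2 to 3 among all genes, and Elane, neutrophil elastase, averaged 10670 ± 1484 TPM and ranked 2 to 4. Ly6c2, a surface marker of classical monocytes, averaged 5651 ± 584 TPM there and ranked 8 to 9. Xist, the transcript of the inactive X chromosome, was at 15.45 to 22.27 TPM in the labelled monocyte libraries and was listed at 0 in all 6 steady-state macrophage libraries, whereas the Y-linked Ddx3y was at 43.59 to 61.07 TPM in the macrophages and 0.0105 to 0.0127 TPM in the labelled monocytes. Sex-linked transcripts thus differed along with cell type in both comparisons. They are reported as comparisons with the libraries labelled blood monocytes.

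**Figure D3:**
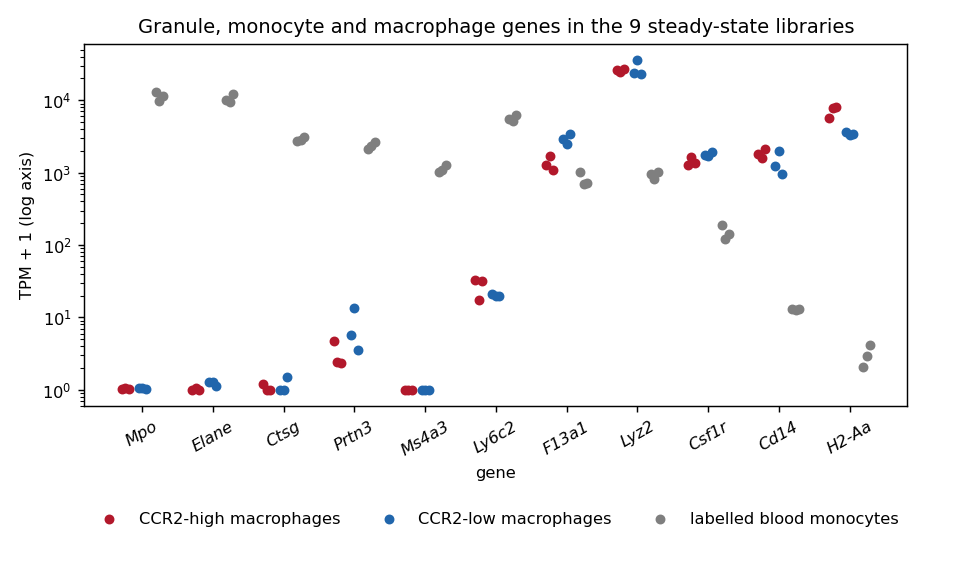
Granule, monocyte and macrophage genes in the 9 steady-state libraries, as TPM + 1 on a log axis; each point is a library, colored by group. Mpo averaged 11290 TPM in the libraries labelled blood monocytes and 0.0395 TPM in CCR2-high macrophages, while Cd14 averaged 11.9 TPM and 1852 TPM.

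Against these libraries, CCR2-high macrophages held far more transcript of MHC class II, complement C1q, chemokine and scavenger receptor genes. They held less of cell-cycle genes and of single granule genes such as Mpo and Elane. Of 15467 genes, 12038 were called, 4106 higher and 7932 lower, and 7078 had an absolute log2 fold change of at least 1. Of the 50 lists, 38 passed, 33 higher and 5 lower, and 2 passed with an estimated correlation. Most genes lay lower on the TPM scale, with a median log2 fold change of -0.42 over all genes, which TMM scaling moved to 0.009, with 5814 genes higher and 5695 lower. Fold changes and calls of genes are given against 0, so this shift is not removed from them.

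Among genes above 0 in both groups, 6 are given per direction. They were ranked on log2(value + 1), which limits the fold change of genes near 0 in 1 group, so their order depends on the pseudocount. Retnla, a secreted product of alternatively activated macrophages, averaged 17460 ± 5802 against 0.0272 ± 0.0471 TPM (log2 fold change 13.99, adjusted p = 1.04e-11). The MHC class II gene H2-Eb1 averaged 8492 ± 1869 against 0.873 ± 0.236 TPM (log2 fold change 12.13, adjusted p = 7.54e-13). H2-Aa averaged 7234 ± 1325 against 2.05 ± 1.06 TPM (log2 fold change 11.26, adjusted p = 1.04e-11). Cd74, the invariant chain, averaged 30760 ± 6514 against 8.49 ± 2.5 TPM (log2 fold change 11.67, adjusted p = 4.95e-12). The activation marker Cd83 averaged 2335 ± 266 against 0.0245 ± 0.0255 TPM (log2 fold change 11.15, adjusted p = 3.79e-14). C1qb averaged 5538 ± 598 against 1.78 ± 0.0622 TPM (log2 fold change 10.96, adjusted p = 3.79e-14). The 6 lower ones were granule genes. Mpo averaged 0.0395 ± 0.0161 against 11290 ± 1559 TPM (log2 fold change -13.40, adjusted p = 3.79e-14). Elane averaged 0.0174 ± 0.0302 against 10670 ± 1484 TPM (log2 fold change -13.35, adjusted p = 3.79e-14). The proteases Ctsg and Prtn3 averaged 0.0686 ± 0.119 against 2892 ± 224 TPM and 2.15 ± 1.34 against 2359 ± 268 TPM, with log2 fold changes of -11.41 and -9.62. Prg2, an eosinophil granule protein gene, averaged 0.0191 ± 0.0332 against 1656 ± 294 TPM (-10.65 in log2 fold change). Prss34, a basophil and mast cell protease gene, averaged 0.678 ± 0.799 against 938 ± 119 TPM (-9.23 in log2 fold change). Ccr2 and Cx3cr1 were higher, with log2 fold changes of 2.92 and 2.08 (adjusted p = 1.79e-09 and adjusted p = 4.16e-06).

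Macrophage lists were almost wholly higher. All 26 of 26 resident macrophage genes were higher, as when adjusted over the list alone, with a median of 6.36 (adjusted p = 9.91e-19, and adjusted p = 0.0894 with an estimated correlation). Mrc1, the mannose receptor, averaged 509.5 ± 82.4 against 0.802 ± 0.28 TPM, log2 fold change 8.14, and Igf1 64.4 ± 3.08 against 0.0292 ± 0.0242 TPM, log2 fold change 5.99. Folr2 averaged 769 ± 213 TPM and was listed at 0 in the labelled monocytes. Core macrophage genes were higher in 18 of 19 and lower in 0, also over the list alone (adjusted p = 1.53e-12, and adjusted p = 0.0508 with an estimated correlation), with Adgre1, which encodes F4/80, at 649.9 ± 51.9 against 7.77 ± 1.48 TPM, log2 fold change 6.22. Scavenger and phagocytic receptors, with 21 of 22 higher and 1 lower, passed both ways (adjusted p = 4.86e-14, and adjusted p = 0.00741 with an estimated correlation). Cd36 averaged 825 ± 137 against 0.0293 ± 0.0404 TPM, log2 fold change 9.63. Chemokines did so too, with 25 of 25 higher (adjusted p = 9.45e-17, and adjusted p = 0.0214 with an estimated correlation). Ccl6 averaged 2550 ± 109 against 12.6 ± 0.496 TPM, log2 fold change 7.55, and Cxcl2 4573 ± 103 against 3.19 ± 1.13 TPM, log2 fold change 10.12. Complement components were higher in 13 and lower in 1 of 17 (adjusted p = 7.22e-09, and adjusted p = 0.0504 with an estimated correlation). C3ar1 (log2 fold change 8.37, adjusted p = 2.58e-12) was an example. MHC class II presentation genes were higher in 14 and lower in 1 of 15 (adjusted p = 9.03e-11, and adjusted p = 0.0578 with an estimated correlation). Interferon-stimulated genes were higher in 33 and lower in 2 of 35 (adjusted p = 1.63e-13, and adjusted p = 0.163 with an estimated correlation). Cxcl10 (718 ± 38.4 against 2.53 ± 1.4 TPM, log2 fold change 7.75) was an example. Counts adjusted over the list alone equaled those over all genes in each of these lists. Lists of other cell types also passed higher, though not with an estimated correlation. Among them were endothelial and mural (13 higher and 3 lower of 24, camera adjusted p = 0.000159) and B cell markers (10 and 1 of 15, 0.000329). Dendritic cell (13 and 4 of 18, 0.000361) and adipocyte markers (10 and 3 of 14, 0.00038) were others. Fibroblast (0.0889) and mesothelial markers (0.0883) did not pass.

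Immediate early and dissociation response genes, which tissue digestion is known to induce, were higher in 24 of 24, also over the list alone, with a median of 4.92 (adjusted p = 2.08e-18, and adjusted p = 0.0508 with an estimated correlation). Atf3 (918 ± 27.6 against 0.0836 ± 0.0351 TPM, log2 fold change 9.73, adjusted p = 3.79e-14) and Gadd45b (972 ± 28.6 against 25.7 ± 1.73 TPM, log2 fold change 5.19) were examples. Cell cycle genes were lower in 39 and higher in 1 of 40, also over the list alone (adjusted p = 1.66e-08, and adjusted p = 0.302 with an estimated correlation). Mcm2 (26.7 ± 4.26 against 276 ± 47 TPM, log2 fold change -3.32) and Tyms, thymidylate synthase (3.72 ± 0.672 against 41.8 ± 1.43 TPM, log2 fold change -3.19) were examples. Nuclear oxidative phosphorylation genes were lower in 35 of 35 (adjusted p = 1.59e-06, and adjusted p = 0.242 with an estimated correlation). Cycs averaged 86.9 ± 4.85 against 321 ± 22.6 TPM, log2 fold change -1.87. Ribosomal protein genes were lower in 77 of 78 (adjusted p = 7.62e-10, and adjusted p = 0.437 with an estimated correlation), and Rpl4 averaged 413 ± 24.6 against 1435 ± 62.4 TPM, log2 fold change -1.79. Both lists had the same counts over the list alone. Their medians, -1.02 and -1.23, became -0.52 and -0.73 under TMM scaling. Eosinophil, basophil and mast cell markers were lower in 13 and higher in 5 of 19, also over the list alone (adjusted p = 0.0105, and adjusted p = 0.336 with an estimated correlation). Mcpt8, a basophil protease, was listed at 0 in CCR2-high and averaged 512 ± 62.7 TPM in the labelled monocytes. This list missed its threshold when any labelled monocyte library was left out (adjusted p 0.249 to 0.285). Neutrophil markers were lower in 12 and higher in 4 of 17, also over the list alone, but the list missed the threshold (adjusted p = 0.0889, and adjusted p = 0.48 with an estimated correlation). Cxcr2 was lower (0.115 ± 0.137 against 6.3 ± 0.949 TPM, log2 fold change -2.71) and Mmp9 higher (140.1 ± 38.7 against 1.87 ± 0.907 TPM, log2 fold change 5.62). Classical monocyte genes split, 8 higher and 7 lower of 19, also over the list alone (adjusted p = 0.153, and adjusted p = 0.423 with an estimated correlation). The median was 0.16, the mean -0.45, and camera's direction higher; the median was 0.64 under TMM scaling and 0.54 under quantile normalization. Ly6c2 (26.3 ± 8.74 against 5651 ± 584 TPM, log2 fold change -7.75, adjusted p = 1.05e-10) and Plac8 (12.4 ± 1.52 against 1435 ± 199 TPM, log2 fold change -6.74) were lower, and Mcub was higher (217 ± 15.4 against 11.8 ± 1.38 TPM, log2 fold change 4.10).

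CCR2-low macrophages differed from the same libraries in a similar number of genes. Resident macrophage and complement genes were higher, and cell-cycle genes and the single granule genes Mpo and Elane were lower. Of 15467 genes, 12225 were called, 4397 higher and 7828 lower, 7651 of them with an absolute log2 fold change of at least 1. Of 50 lists, 39 passed, 34 higher and 5 lower, and 2 passed with an estimated correlation. The median over all genes was -0.401, and 0.035 under TMM scaling, which gave 6227 genes higher and 5815 lower.

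Retnla was again the gene with the largest increase, at 35000 ± 10580 against 0.0272 ± 0.0471 TPM (log2 fold change 15.01, adjusted p = 5.76e-12). C1qb averaged 6461 ± 445 against 1.78 ± 0.0622 TPM (log2 fold change 11.18, adjusted p = 3.88e-14). C1qc and C1qa averaged 3210 ± 296 against 0.736 ± 0.414 TPM and 4081 ± 404 against 1.22 ± 0.531 TPM, with log2 fold changes of 10.88 and 10.86. The C-type lectin gene Cd209f averaged 2557 ± 362 against 0.127 ± 0.0875 TPM (log2 fold change 11.14, adjusted p = 1.25e-11). H2-Eb1 averaged 3790 ± 263 against 0.873 ± 0.236 TPM (log2 fold change 10.99, adjusted p = 1.6e-12). Among decreases, Mpo averaged 0.0507 ± 0.0318 against 11290 ± 1559 TPM (log2 fold change -13.38, adjusted p = 3.88e-14). Elane averaged 0.223 ± 0.0954 against 10670 ± 1484 TPM (log2 fold change -13.09, adjusted p = 3.88e-14). Ctsg and Prg2 had log2 fold changes of -11.29 and -10.65. Prss34 averaged 0.564 ± 0.644 against 938 ± 119 TPM (log2 fold change -9.30, adjusted p = 1.21e-09). Plac8 averaged 2.84 ± 1.05 against 1435 ± 199 TPM (log2 fold change -8.58, adjusted p = 3.13e-11). Ccr2 was higher in CCR2-low than in the labelled monocytes (log2 fold change 0.36, adjusted p = 0.0104), with a log2 fold change of 0.86 under TMM scaling, and Cx3cr1 lower (log2 fold change -2.40, adjusted p = 1.11e-06).

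By list, all 26 of 26 resident macrophage genes were higher in CCR2-low, with a median of 7.87 (adjusted p = 1.14e-18, and adjusted p = 0.0994 with an estimated correlation); Timd4 averaged 208 ± 20.2 TPM and was listed at 0 in the labelled monocytes. Core macrophage genes were higher in 18 of 19 and lower in 0 (adjusted p = 1.03e-11, and adjusted p = 0.0661 with an estimated correlation). Mertk, a receptor for apoptotic cells (72.1 ± 4.32 against 0.0278 ± 0.0281 TPM, log2 fold change 6.15) was an example. Scavenger and phagocytic receptors (20 of 22 higher, 1 lower; adjusted p = 4.32e-12, and adjusted p = 0.0114 with an estimated correlation) and chemokines (25 of 25 higher; adjusted p = 5.07e-15, and adjusted p = 0.0287 with an estimated correlation) passed both ways, with Mrc1 at 769.5 ± 112 against 0.802 ± 0.28 TPM, log2 fold change 8.74 and Ccl2 at 448 ± 36.9 against 0.354 ± 0.14 TPM, log2 fold change 8.38. Complement components were higher in 15 of 17 and lower in 0 (adjusted p = 1.7e-09, and adjusted p = 0.0521 with an estimated correlation). C5ar1 (log2 fold change 8.76, adjusted p = 1.88e-12) was an example. MHC class II genes were higher in 14 and lower in 1 of 15 (adjusted p = 6.5e-09, and adjusted p = 0.0825 with an estimated correlation). Cd86 (log2 fold change 5.80, adjusted p = 9.8e-12) was an example. Interferon-stimulated genes were higher in 30 and lower in 1 of 35 (adjusted p = 4.95e-11, and adjusted p = 0.214 with an estimated correlation). Ifi204 (log2 fold change 4.18, adjusted p = 8.82e-11) was an example. Adjusted over the list alone, the counts of these lists were the same. Lists of other cell types also passed higher, though not with an estimated correlation. Among them were endothelial and mural (20 higher and 1 lower of 24, camera adjusted p = 1.27e-07) and adipocyte markers (10 and 3 of 14, 0.000217). B cell (12 and 1 of 15, 0.00063), mesothelial (10 and 2 of 14, 0.00173) and fibroblast markers (11 and 4 of 18, 0.00315) were others.

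Immediate early and dissociation response genes were higher in 23 of 24 (adjusted p = 7.4e-16, and adjusted p = 0.0706 with an estimated correlation). Egr2 (125 ± 8.87 against 0.112 ± 0.0564 TPM, log2 fold change 6.83) was an example. Cell cycle genes were lower (39 lower and 1 higher of 40; adjusted p = 7.65e-10, and adjusted p = 0.259 with an estimated correlation), with Mcm5 at 10.8 ± 0.86 against 336 ± 68.5 TPM, log2 fold change -4.83. Also lower were nuclear oxidative phosphorylation genes (35 of 35; adjusted p = 5.1e-07, and adjusted p = 0.227 with an estimated correlation), with Cyc1 at 100.2 ± 7.77 against 345 ± 12.8 TPM, log2 fold change -1.77. Ribosomal protein genes were lower too (78 of 78; adjusted p = 5.96e-12, and adjusted p = 0.378 with an estimated correlation), with Rpsa at 194 ± 25.2 against 988 ± 36.6 TPM, log2 fold change -2.35. The oxidative phosphorylation and ribosomal medians, -1.09 and -1.62, became -0.59 and -1.12 under TMM scaling. Eosinophil, basophil and mast cell markers were lower in 13 and higher in 6 of 19 (adjusted p = 0.0226, and adjusted p = 0.378 with an estimated correlation), and this list missed its threshold when any labelled monocyte library was left out (adjusted p 0.406 to 0.455) and at a pseudocount of 0.1 (adjusted p = 0.0633). The neutrophil list, with 11 lower and 3 higher of 17, and the classical monocyte list, with 7 higher and 9 lower of 19, did not pass. The values were adjusted p = 0.0803, and adjusted p = 0.452 with an estimated correlation for the former, and adjusted p = 0.725, and adjusted p = 0.828 with an estimated correlation for the latter. For classical monocyte genes the median was -0.42 and the mean -1.12 while camera's direction was higher, and TMM scaling brought the median to 0. Ly6c2 was lower (19.3 ± 0.638 against 5651 ± 584 TPM, log2 fold change -8.12) and Ifitm6 higher (234 ± 25.4 against 23.4 ± 2.7 TPM, log2 fold change 3.27). Counts adjusted over the list alone were the same for these lists except classical monocyte genes, with 8 higher and 9 lower.

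CCR2-high libraries were placed on the axis from the labelled monocytes (0) to CCR2-low macrophages (1). Over 11892 genes, chosen because they differ between those ends, the median position was 0.88, 0.922 and 0.937 in the 3 libraries, a mean of 0.913 ± 0.029 (SD). The share of these genes nearer to the CCR2-low level was 86.6, 91.6 and 90.2%. CCR2-low libraries left out in turn, of the choice of genes too, lay at 1.004, 0.985 and 0.986, where CCR2-high libraries averaged 0.925, 0.917 and 0.919. The value describes a place relative to these labelled monocyte libraries, which differ in sex-linked transcripts and hold granule genes of precursors. Under the authors' own limit of 1e-04, 4580 genes differed for CCR2-high and 5301 for CCR2-low from these libraries. Of the 4362 and 4894 tested here, 4332 and 4889 were called in the same direction and 0 in the opposite one. At an adjusted p below 0.05 the authors' values gave 7170 and 7989 genes, against 12038 and 12225 called here.

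CCR2-low macrophages from mice after MI were compared with those from sham-operated mice, to ask whether MI alters this subset. Transcripts typical of adipocytes, fibroblasts, mesothelium, neutrophils and large peritoneal macrophages were higher as lists after MI, and cell-cycle, MHC class II and interferon-stimulated lists were lower, at camera's preset correlation and not with an estimated one. No single gene passed: of 9607 genes, limma called 0, the smallest adjusted p being 0.241, with 753 genes at an unadjusted p below 0.05, and voom also called 0, with 497. Chance alone gives a share of 0.05 of genes under that limit, and voom tested only genes whose reads could be worked back. In the simulated design 72% of genes with a log2 change of 1 were recovered, and 0% at 0.5. That simulation drew independent noise and held no outlying library, so recovery in these libraries may be lower. Of the 46 lists tested, 24 passed the camera test, 14 higher and 10 lower, and 0 passed with an estimated correlation.

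The genes with the smallest p are given although none passed. Above sham, Lrg1, an acute-phase glycoprotein, averaged 46.3 ± 14.2 against 14.6 ± 0.653 RPKM (log2 fold change 1.56, adjusted p = 0.241). Cfd, the adipocyte-secreted complement factor D, averaged 47.4 ± 18.9 against 9.39 ± 2.63 RPKM (log2 fold change 2.18, adjusted p = 0.241). Serpinb2 averaged 47.8 ± 19.7 against 14.8 ± 0.515 RPKM (log2 fold change 1.56, adjusted p = 0.339). Car3, carbonic anhydrase 3, averaged 20.2 ± 7.34 against 6.22 ± 0.904 RPKM (log2 fold change 1.49, adjusted p = 0.37). Below sham, Adk, adenosine kinase, averaged 20.1 ± 1.38 against 30 ± 1.34 RPKM (log2 fold change -0.55, adjusted p = 0.339). Ms4a7 averaged 55.9 ± 6.5 against 90.3 ± 8.91 RPKM (log2 fold change -0.68, adjusted p = 0.37). Cd300lb averaged 26.1 ± 1.22 against 39.4 ± 4.64 RPKM (log2 fold change -0.57, adjusted p = 0.37). H2-Q7 averaged 52.9 ± 17.4 against 109.8 ± 7.57 RPKM (log2 fold change -1.08, adjusted p = 0.37). Over all genes tested, 14.6% showed no overlap between the groups, where chance gives 10%. With MI replicate 3 left out, 5 genes passed, all higher: Gpx3 (log2 fold change 2.19), Sparcl1 (1.49), Car3 (1.81), Cidec (1.68) and Ctla2b (1.27). Gpx3, Sparcl1 and Ctla2b were named after their values were seen.

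Markers of stromal cells were higher after MI as lists. The fibroblast and preadipocyte list passed (adjusted p = 5.24e-10, and adjusted p = 0.375 with an estimated correlation), with 13 of 15 members above sham, a median log2 fold change of 0.76 and, adjusted over the list alone, 10 members called higher and 1 lower. Examples were the collagen gene Col3a1 (9.1 ± 2.27 against 4.39 ± 1.27 RPKM, log2 fold change 0.91), Sparc (10.4 ± 0.712 against 6.45 ± 1.39 RPKM, log2 fold change 0.62) and Dpt (3.08 ± 0.584 against 1.33 ± 0.412 RPKM, log2 fold change 0.81). Adipocyte markers passed as well (adjusted p = 1.49e-07, and adjusted p = 0.348 with an estimated correlation), with 11 of 12 above sham and 6 called adjusted over the list alone. Of these 12 genes, 6 also belong to another fixed list, such as lipid uptake and storage, and had a median of 0.07; the 6 in no other list had a median of 1.36. Adipoq, adiponectin (3.88 ± 0.682 against 1.09 ± 0.4 RPKM, log2 fold change 1.24), and Cidec, a lipid droplet protein (5.41 ± 1.45 against 1.25 ± 0.244 RPKM, log2 fold change 1.49) were examples. All 10 of 10 mesothelial markers were above sham, with 0 called over the list alone (adjusted p = 6.48e-06, and adjusted p = 0.375 with an estimated correlation). Efemp1 (7.07 ± 1.41 against 3.19 ± 1.51 RPKM, log2 fold change 1.00) was an example. In each of these 3 lists the mean log2 level of every MI library lay above that of every sham library, for example 2.94 to 3.27 against 2.32 to 2.57 for adipocyte markers. The endothelial and mural list, with 8 measured members, also passed the camera threshold. It missed that threshold in 2 of 15 alternatives (highest adjusted p = 0.136).

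Myeloid and blood cell lists differed as well. Large peritoneal macrophage genes (11 of 12 above sham, 5 called over the list alone; adjusted p = 5.54e-09, and adjusted p = 0.263 with an estimated correlation) included Lrg1 and Prg4 (16.9 ± 6.83 against 5.87 ± 0.455 RPKM, log2 fold change 1.31). Neutrophil markers (8 of 9, 4 called over the list alone; adjusted p = 2.11e-05, and adjusted p = 0.375 with an estimated correlation) included G0s2 (15.5 ± 4.01 against 3.32 ± 2.76 RPKM, log2 fold change 2.09) and the calprotectin genes S100a8 (66.8 ± 19 against 28.8 ± 12.8 RPKM, log2 fold change 1.24) and S100a9 (62.9 ± 12 against 23.6 ± 16.5 RPKM). Platelet and erythroid markers (5 of 5, 3 called over the list alone; adjusted p = 7.98e-05, and adjusted p = 0.375 with an estimated correlation) were globins in 4 of 5. Hba-a1 (40.9 ± 18 against 12.8 ± 6.14 RPKM, log2 fold change 1.57) was an example. Resident macrophage genes were above sham in 26 of 26, with a median of 0.56 and 0 called over the list alone (adjusted p = 1.23e-07, and adjusted p = 0.524 with an estimated correlation). Timd4 (86.9 ± 29.7 against 47.6 ± 6.1 RPKM, log2 fold change 0.81) and Ltc4s (197 ± 12.2 against 136 ± 29.9 RPKM, log2 fold change 0.55) were examples. The mean level of this list was 8.08, 7.19 and 6.40 in the MI libraries and 6.03, 6.78 and 6.72 in the sham libraries, so MI replicate 3 lay below 2 sham libraries. Its median fell to 0.29 without MI replicate 1 and 0.37 without sham replicate 1, and was 0.96 without MI replicate 3. B cell markers were below sham in 9 of 11, with 1 called lower over the list alone (adjusted p = 0.00189, and adjusted p = 0.49 with an estimated correlation), such as Cd22 (0.914 ± 0.223 against 2.42 ± 0.595 RPKM, log2 fold change -0.83), and missed the threshold without MI replicate 3 (adjusted p = 0.0724) and with a mean of at least 5 (adjusted p = 0.251).

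Lists of cell states differed too. Cell cycle genes were below sham in 36 of 37, with a median of -0.55 and 0 called over the list alone (adjusted p = 2.65e-12, and adjusted p = 0.457 with an estimated correlation). The median was -0.30 without MI replicate 1, whose mean level was 1.93 against 2.54 and 2.63 in the other MI libraries. Aurkb (5.78 ± 1.93 against 10.2 ± 0.891 RPKM, log2 fold change -0.77) and Mcm2 (5.33 ± 1.13 against 7.83 ± 0.668 RPKM, log2 fold change -0.49) were examples. MHC class II genes were below sham in 12 of 14, 1 called lower over the list alone (adjusted p = 0.000274, and adjusted p = 0.386 with an estimated correlation). H2-DMb2 (3.5 ± 0.547 against 6.45 ± 1.09 RPKM, log2 fold change -0.72) was an example. Interferon-stimulated genes were below sham in 26 of 36, 2 called lower over the list alone (adjusted p = 0.00175, and adjusted p = 0.579 with an estimated correlation). Mx1 (4.12 ± 0.441 against 6.51 ± 0.505 RPKM, log2 fold change -0.56) and Irf7 (77.3 ± 11.3 against 112 ± 13.6 RPKM, log2 fold change -0.53) were examples. Nuclear oxidative phosphorylation genes were below sham in 35 of 35, 0 called over the list alone (adjusted p = 0.000176, and adjusted p = 0.634 with an estimated correlation), with a median of -0.17. Of the RNA-quality lists, those of mitochondrially encoded and ribosomal protein genes lay the same way. Mitochondrially encoded genes were below sham in 13 of 13, with a median of -0.24 and 0 called over the list alone (adjusted p = 0.00491, and adjusted p = 0.579 with an estimated correlation), and missed the threshold without MI replicate 3 (adjusted p = 0.0841) or sham replicate 3 (0.0736) and with a score for CCR2-high genes as covariate (0.0811). Ribosomal protein genes were below sham in 72 of 77, with a median of -0.12 and 0 called over the list alone (adjusted p = 0.000274, and adjusted p = 0.763 with an estimated correlation), and missed it without MI replicate 1 (adjusted p = 0.917) or sham replicate 3 (0.0545). Glucocorticoid response genes were above sham in 12 of 15, 2 called higher and 1 lower over the list alone (adjusted p = 9.68e-05, and adjusted p = 0.263 with an estimated correlation). Klf9 (3.11 ± 1.2 against 1.19 ± 0.13 RPKM, log2 fold change 0.86) and Per1 (5.08 ± 0.628 against 3.57 ± 0.4 RPKM, log2 fold change 0.41) were examples. Heat shock genes (12 of 15 above sham, 1 called over the list alone; adjusted p = 9.68e-05, and adjusted p = 0.386 with an estimated correlation) and immediate early genes (20 of 23 above sham, 0 called over the list alone; adjusted p = 0.000176, and adjusted p = 0.531 with an estimated correlation) were higher. Hspb1 averaged 9.8 ± 1.1 against 6.29 ± 0.875 RPKM, log2 fold change 0.57, and Dusp1 1149 ± 86.5 against 905 ± 71.8 RPKM, log2 fold change 0.34.

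Of the 24 lists past the threshold, 6 stayed past the threshold in their direction under all 15 or 16 alternatives run at the preset correlation: adipocyte, fibroblast, mesothelial, neutrophil, large peritoneal macrophage and glucocorticoid response genes. Without MI replicate 1, which had a mean correlation of 0.959 with the other libraries where these had 0.98 to 0.984, 24 lists passed, 17 of them among the 24 of the full set; the oxidative phosphorylation list (adjusted p = 0.436) and the immediate early list (adjusted p = 0.111) no longer did. Without MI replicate 2 the interferon list (adjusted p = 0.243) and the MHC class II list (adjusted p = 0.0962) did not pass, and the interferon list also missed the threshold without sham replicate 1 (adjusted p = 0.0796). With a score for CCR2-high genes as covariate, the resident macrophage, oxidative phosphorylation and ribosomal protein lists turned direction (adjusted p = 0.0102, 0.00114 and 0.00217). The cell cycle (adjusted p = 0.0615), interferon (0.448), heat shock (0.349), immediate early (0.482) and platelet and erythroid (0.0553) lists did not pass in that fit. The genes of the score include members of the resident macrophage and cell cycle lists, such as Timd4 and Mcm2. The score also followed the groups, so that fit cannot decide what these lists depend on.

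Other list medians after MI also depended on single libraries. Without MI replicate 1 they were -0.02 for oxidative phosphorylation (-0.17 with all libraries), -0.01 for ribosomal protein (-0.12), 0.14 for immediate early (0.34) and 0.08 for heat shock genes (0.26). Without MI replicate 2 they were -0.15 for MHC class II (-0.48) and -0.15 for B cell genes (-0.55). Without MI replicate 3 they were -0.32 for interferon (-0.18) and -0.28 for oxidative phosphorylation genes. Leaving out sham replicate 1 gave -0.09 for interferon genes. Leaving out sham replicate 2 gave 0.48 for fibroblast (0.76) and 0.44 for mesothelial markers (0.70), and leaving out sham replicate 3 gave -0.24 for B cell markers.

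**Figure D4:**
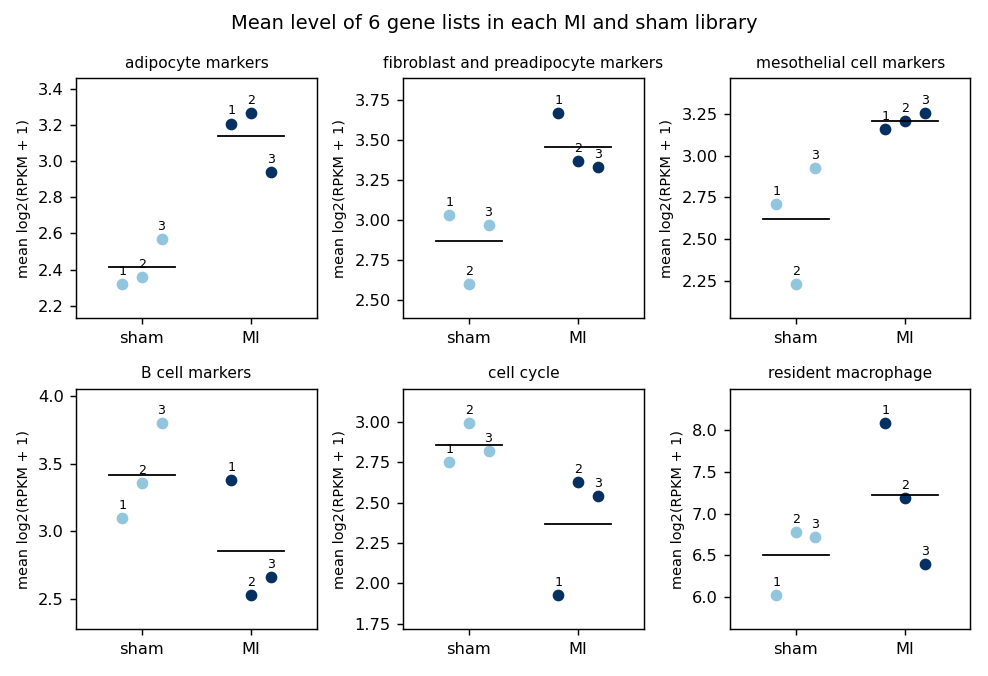
Mean log2(RPKM + 1) of 6 gene lists in each sham and MI library; points are libraries numbered by replicate and lines are group means. Adipocyte, fibroblast and mesothelial lists lie higher in each MI library than in each sham library, while MI replicate 1 has the highest resident macrophage level, 8.08, and the lowest cell cycle level, 1.93.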

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

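The voom fits, the score covariate, camera under some settings and the position with libraries left out were chosen after the data were seen; the other alternatives were fixed beforehand. In the CCR2-high against CCR2-low comparison the 2733 genes became 845 with an absolute log2 fold change of at least 1 (the limit itself removes genes), 1795 with a replicate block and 1524 with voom, which tested fewer genes (8360). Deviations from the group mean correlated at -0.03, -0.36 and -0.22 between libraries of the same number, so libraries of 1 number did not deviate together. Leaving out 1 library gave 1481 to 2424 genes there, 10924 to 11595 for CCR2-high against labelled monocytes, 11208 to 11717 for CCR2-low against them and 0 to 5 for MI against sham, with fewer libraries in each fit. The counts of 12038 and 12225 became 7078 and 7651 with the fold change limit, which itself removes genes, and 6387 and 6496 with voom over 8360 genes. In these comparisons the share of called genes that were higher rose from 34.1 and 36% to 50.5 and 51.7% under TMM scaling and to 41.7 and 42.9% under quantile normalization. Beyond these and the covariate fit, each count of genes stayed within 1.5 times its value under every alternative run.

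With an estimated correlation the numbers of lists past the threshold were 0, 2, 2 and 0 in the order of the report, instead of 25, 38, 39 and 24. Leaving out 1 library gave 23 to 26, 35 to 39, 36 to 39 and 19 to 24 lists. At the preset correlation 17, 33, 32 and 6 of those lists kept their direction and side of the threshold under all alternatives. Median log2 fold changes of the lists described with named members had the same sign under TMM scaling and quantile normalization. Classical monocyte genes were at 0 under TMM scaling for CCR2-low against labelled monocytes. Of the values of single named genes other than Ccr2 and Cx3cr1 under alternatives, 1205 of 1219, 857 of 857, 872 of 872 and 1061 of 1065 kept direction and side; 14 in the first comparison lost the call, Cox5a and Sdhb turned direction after MI, and Car3 and Cidec gained it without MI replicate 3 (both adjusted p = 0.0353). The range of the log2 fold change over all alternatives was 2.46 to 2.62 for Ccr2 and 3.34 to 4.99 for Cx3cr1 in CCR2-high against CCR2-low. After MI it was wider for its size, at -1.232 to -0.012 for Ccr2 and -0.978 to 0.239 for Cx3cr1. Cx3cr1 ran from -2.839 to -1.508 in CCR2-low against labelled monocytes. The position of 0.913 was 0.895 over genes with an absolute log2 fold change of at least 2 and 0.91 at a pseudocount of 0.1, and 0.917 to 0.925 with 1 CCR2-low library left out.

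With the CCR2-high score as covariate in the MI comparison, 3 genes passed, all higher: Marco (log2 fold change 1.77), Stfa3 (2.68) and Gm28592 (1.38), named after their values were seen (adjusted p = 0.0428 for each). Several results then turned direction: the resident macrophage list (adjusted p = 0.0102), cholesterol biosynthesis (0.243), oxidative phosphorylation (0.00114), alternative activation (0.136), immediate early genes (0.482), NK and ILC markers (0.836) and ribosomal proteins (0.00217), and the log2 fold changes of Cx3cr1 (0.239), Cox5a (0.031) and Sdhb (0.042), none of the 3 genes past the threshold. In that setting 23 lists passed, 13 of them among the 24. The cholesterol biosynthesis list also turned direction without MI replicate 2 (adjusted p = 0.967), and with 1 library left out its adjusted p ran from 2.16e-06 to that value. The score followed the groups, at -0.88 to 0.81 in MI and 0.87 to 1.21 in sham libraries. Its genes include members of the resident macrophage list, such as Timd4. The covariate fit therefore cannot decide on the cause of these turns, which was not tested. A replicate block by title number or by description number left 0 genes called. A DESeq2 or edgeR fit on raw counts was not run, because the tables hold TPM and RPKM. The voom alternative is limited to genes whose reads could be worked back. At a log2 change of 0.5 the simulated design recovered 0% of genes in the MI comparison.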

Other observations

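The tests of later neutrophil stages, of CCR2-high cell share and depth in MI replicate 1, and of stromal RNA were chosen after the results they measure were seen. Further fixed lists, not described in the report, also differed. In CCR2-high against CCR2-low macrophages, apoptosis genes were called higher in 7 of 22 and lower in 0 (adjusted p = 0.000306, and adjusted p = 0.346 with an estimated correlation), and interferon-stimulated genes higher in 9 and lower in 1 of 35 (adjusted p = 0.0234, and adjusted p = 0.794 with an estimated correlation). The interferon list missed its threshold in 5 of 15 alternatives: a mean of at least 5 (adjusted p = 0.127), quantile normalization (0.0806), and without CCR2-high replicate 2 (0.0769), CCR2-high replicate 3 (0.331) or CCR2-low replicate 3 (0.282). NK and ILC markers were higher in 4 of 8 (adjusted p = 0.0165, and adjusted p = 0.331 with an estimated correlation), a result lost in a fit of only the 6 libraries compared (adjusted p = 0.0843). Glycolysis (adjusted p = 0.365), hypoxia response (adjusted p = 0.987) and lysosome genes (adjusted p = 0.365) did not pass in that comparison. Against the labelled monocytes, glucocorticoid response genes were higher in 13 of 18 in CCR2-high (adjusted p = 4.52e-07, and adjusted p = 0.0589 with an estimated correlation) and in 14 of 18 in CCR2-low (adjusted p = 1.02e-06, and adjusted p = 0.077 with an estimated correlation), and iron and haem handling genes in 16 (adjusted p = 1.85e-09, and adjusted p = 0.0504 with an estimated correlation) and 16 of 19 (adjusted p = 7.4e-09, and adjusted p = 0.0521 with an estimated correlation).

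After MI, alternative activation genes were above sham in 15 of 17, with a median log2 fold change of 0.36 (adjusted p = 0.013, and adjusted p = 0.492 with an estimated correlation), and matrix and remodelling genes in 14 of 18 (adjusted p = 0.00971, and adjusted p = 0.386 with an estimated correlation). The first of these missed its threshold without MI replicate 1 (adjusted p = 0.0776) and without a filter (0.0792), and the second without MI replicate 3 (0.124). Inflammatory cytokines (adjusted p = 0.971), NF-kB targets (adjusted p = 0.387) and hypoxia response genes (adjusted p = 0.794) did not pass. In MI and sham libraries Xist was at 3.17 to 8.02 RPKM and Ddx3y was listed at 0.

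The libraries labelled blood monocytes held Mpo, Elane, Ctsg (2892 TPM) and Prtn3 (2359 TPM) among their most abundant transcripts, with Ms4a3 at 1136 TPM, Myb at 237 TPM and Kit at 110 TPM. Marker lists for this test were written after the granule genes had been seen, and 4 mature genes already looked at, Cd14, Csf1r, Ccr2 and Cx3cr1, were left out. The ratio of the median of 11 early progenitor genes (94, 85 and 92.7 TPM) to that of 12 mature monocyte genes (50.3, 45 and 47 TPM) was at least 1.87 in each library, so myeloid progenitors in place of blood monocytes may account for the pattern. Ly6c2 and Lyz2 were not among the 12 either. Of the genes not listed, Ly6c2 (5651 TPM), Lyz2 (936 TPM), Csf1r (151 TPM) and Ccr2 (58.9 TPM) lay above the mature median. Cd14 (11.9 TPM) and Cx3cr1 (15.3 TPM) lay below it. The ratio depends on the genes listed and was not computed with these added. Later neutrophil stages as the main source are argued against, since the median of secondary granule and late neutrophil genes was at most 0.00281 of the primary granule median. The primary granule median comes from the 4 genes that define the pattern, so this ratio cannot exclude a smaller share of such cells. Single members averaged up to 461 TPM (S100a8). Ly6c2 at 5651 TPM leaves a mixture or monocyte-committed progenitors open, both untested, as is a difference between the mice, whose Xist and Y-linked transcripts differed from those of the macrophage libraries.

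MI replicate 1 stood apart, with Lyve1 at 253 RPKM against 33.2 to 80 RPKM in the other 5 libraries and a mean correlation of 0.959 with them. Lower depth is argued against, as 1 library, sham replicate 2, had fewer reads worked back (32.68 against 36.24 M) and a higher mean correlation (0.983). Across the 1637 genes called between the steady-state subsets and measured here, which are not independent replicates, the deviation of MI replicate 1 from the other MI libraries correlated at -0.63 with the CCR2-high minus CCR2-low change. The same measure ran from -0.27 to 0.42 in sham libraries and was 0.25 and 0.63 in MI replicates 2 and 3. Each was taken against the other libraries of its group, so the values within a group depend on each other. The value of -0.63 may reflect fewer CCR2-high cells in that library, as a hypothesis. A stronger response to MI in that sample stays open and was not tested. With RPKM brought to the total of TPM, its Ccr2 of 21.2 lay below steady-state CCR2-low libraries (66.3 to 83.2). Fewer CCR2-high cells alone would not give that value if CCR2-low cells of both sets were alike. Its Cx3cr1 of 13.4 stayed above theirs (1.59 to 2.55).

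Adipocyte (6 of 12 genes also in another fixed list), fibroblast and mesothelial transcripts were higher after MI as lists at the preset correlation, but not with an estimated correlation (adjusted p = 0.348, 0.375 and 0.375). Of 9607 genes limma called 0 (753 at an unadjusted p below 0.05), and voom called 0 (497) of those whose reads could be worked back. All 3 lists still passed, higher, without MI replicate 1 (3 of 3), which argues against MI replicate 1 alone, at the preset correlation. They also passed with the CCR2-high score as covariate (3 of 3), but that fit cannot decide on a different share of CCR2-high cells. The score followed the groups, at -0.88 to 0.81 in MI and 0.87 to 1.21 in sham libraries. Its genes also came from a contrast in which these marker lists were lower. A different share of CCR2-high cells, stromal RNA or cells carried into the sort, and an effect of MI on the macrophages themselves all stay open. That all 3 lists (3 of 3) lay higher in each MI library than in each sham library restates the pattern and decides for none of these. The B cell list was lower, so markers of other cell types did not all move together.

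For each comparison the 6 libraries form 10 splits, too few for a share under 0.05. The real counts were 2733, 12038, 12225 and 0 genes, and the highest counts of other splits were 1, 0, 0 and 0. A count as large as the real one was reached by 1, 1, 1 and 10 splits, the real one included.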
